A study of Mus musculus with 24 samples.

How the data were processed

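RNA was sequenced from the hippocampus of adult male C57BL/6 mice that carry RiboTag, an epitope-tagged copy of the ribosomal protein Rpl22 that is switched on by Cre recombinase. In these mice Cre was driven by the promoter of CaMKIIα, a gene of excitatory forebrain neurons, so ribosomes of Cre-positive cells could be pulled down from a lysate with an antibody to the tag. The labels give 12 mice and 24 libraries: from each mouse an input library of the whole lysate and a library of the immunoprecipitate. Conditional knock-in (cKI) mice hold eIF2α with its phosphorylated serine replaced by alanine on both alleles, and a floxed transgene of normal eIF2α that Cre removes. Control mice carry Cre without the knock-in. Mice were taken naive or 1 h after fear conditioning, in which a tone is paired with a foot shock. Genotype, training state and fraction make 8 groups of 3 libraries.

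The deposited table holds raw counts per gene for each library, with 51733 genes, each given as a gene symbol with 1 Ensembl transcript identifier. The submitters' processing notes name cutadapt, Bowtie and DESeq2 without saying what each did. The counting tool, the genome build and the strand setting of the counts are not given in the sources used here. Because the build is unknown, no positions are printed, and gene order was taken from the RefSeq annotation of the GRCm38.p6 assembly for names and neighbours alone. Of the symbols, 47597 (92%) matched the gene name table used for lookups. A further 26 symbols had been turned into dates, and 4 genes shared such a symbol. No column of the table was left out.

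Total counts ranged from 28.8 to 43.5 M per library, with 28.8 to 37.7 M in inputs and 30.6 to 43.5 M in immunoprecipitates. At the lowest depth 1 count equals 0.035 CPM (counts scaled to a common library total). The SD printed beside a group mean is the spread between mice in CPM, and "SE" is the standard error of a log2 fold change.

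Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Libraries of 1 fraction were fitted together with 1 mean per group, TMM scaling and the filterByExpr rule for low counts, which left 15238 genes in immunoprecipitates, 17232 in inputs and 17453 in all 24 libraries. Each comparison used the robust quasi-likelihood test of edgeR, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Within each fraction the contrasts were cKI against control in naive mice, 1 h after conditioning and as the mean of both, 1 h against naive in each genotype, and the genotype by training interaction. Across fractions they were immunoprecipitate against input and how that ratio differed with genotype or training. The "mean of both training states" compares 6 mice with 6. Other tests in this text are two-sided unless stated.

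Before the data were examined, 32 lists with 830 genes were fixed: immediate-early and late response genes; ATF4 targets of the integrated stress response; transcripts with upstream open reading frames sensitive to eIF2α; endoplasmic reticulum chaperones; heat shock genes; eIF2 and other initiation factors; cytosolic and mitochondrial ribosomal proteins; nuclear and mitochondrial genes of oxidative phosphorylation; synaptic plasticity, glucocorticoid, clock, cholesterol synthesis and interferon genes; and markers of excitatory neurons, dentate granule cells, CA1 and CA3 pyramidal cells, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, vessels, choroid plexus with ependyma, blood, leptomeninges, thalamus, striatum and cortex. Each list was tested against all other genes with camera in limma, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all lists and contrasts of a fraction. Camera was repeated with the correlation estimated per list, and fry tested each list by itself. Of 196 calls with the preset correlation, 0 passed adjustment with the estimated one, 37 had an unadjusted p under 0.05 there, and 39 passed with fry. The median, the mean and the direction of the test did not differ in sign for any called list.

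The genes named were chosen by a rule fixed with the lists. For each contrast it takes the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups, without clone names. Mean and interaction contrasts drop the overlap condition. With fewer than 5 such genes it takes the 5 smallest p. It adds up to 4 members of each list and a fixed set that includes Eif2s1, Rpl22, Camk2a, Gad1, Gfap, Mbp, Atf4 and Fos. Some genes that the rule chose are not reported and were left out of the named genes without replacement. The text prints a selection of the others, and says so where a gene was picked after its values were seen.

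Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, the replicate number or the mouse as a block, sequencing lane as a covariate, single lanes, only the groups compared, and each library left out in turn. Lane as a covariate, single lanes and only the groups compared were run within a fraction, not for immunoprecipitate against input or its ratios. A granule cell score as a covariate, lane together with 1 library left out, and gene lists without each library were added after the data had been seen. The method was tested on simulated data with known changes in the same design. For naive genotype in immunoprecipitates it called 37 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 64 of 66 changed 4-fold. It also called 9 of 14998 unchanged genes. Simulated genes varied independently of each other, with no differences of lane or granule cells. These counts therefore do not give the error rate in the real libraries. Libraries were also checked for duplicates, and none was found: over 24 pairs of libraries the lowest chi-square per gene was 2.21.

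Sequencing lane differs between groups. Among inputs, lane 4 held the 6 cKI libraries and naive control replicates 1 and 2, and lane 5 held the rest. Among immunoprecipitates, lane 5 held the naive cKI libraries and replicate 1 of cKI at 1 h, and lane 6 held the rest. No lane held both genotypes of the inputs at 1 h or of the naive immunoprecipitates. A lane effect is therefore estimated in each fraction from 1 library that separates lane from group. It is naive control replicate 3 in inputs and cKI replicate 1 at 1 h in immunoprecipitates.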

Results

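The 24 libraries paired a whole-lysate input with a RiboTag immunoprecipitate from each of 12 mice, with 3 mice in each combination of genotype and training state. Total counts were 28.8 to 37.7 M per input and 30.6 to 43.5 M per immunoprecipitate. Between 22130 and 23453 genes had a count in an input, and between 19915 and 20749 in an immunoprecipitate. Genes of the mitochondrial genome took 2.86 to 3.36% of input counts and 0.0893 to 0.155% of immunoprecipitate counts. Replicate 3 of the naive cKI inputs stood apart in single genes. In it 150 genes lay over 4-fold from the mean of the other 2 inputs of its group, against 4 to 52 genes for the other inputs. Over all genes its median absolute deviation was 0.09. By that measure naive control input replicate 2 lay farthest from its group, at 0.188, with the next highest value at 0.127 (naive control replicate 3).

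Transcripts of Eif2s1, which encodes eIF2α, and of Atf4, the transcription factor whose translation rises when eIF2α is phosphorylated, differed between genotypes in opposite directions. Eif2s1 (ENSMUST00000071230) was at 32.0 ± 1.26 CPM (SD, n = 6) in control inputs and 38.3 ± 1.96 in cKI inputs, a log2 fold change of 0.28 (SE 0.04, edgeR adjusted p 0.0024). Atf4 (ENSMUST00000109605) was at 108 ± 7.99 CPM in control inputs and 84.6 ± 3.22 in cKI inputs, a log2 fold change of -0.33 (SE 0.04, edgeR adjusted p 0.0016). In immunoprecipitates Eif2s1 rose from 45.8 ± 2.57 to 53.2 ± 1.95 CPM (log2 0.22, SE 0.04, edgeR adjusted p 0.032). Atf4 fell there from 158 ± 15.3 to 117 ± 17.6 CPM (log2 -0.43, SE 0.07, edgeR adjusted p 0.01). The gene-level count adds the mutant, normal and transgene copies of Eif2s1, so it does not show which copy a mouse carries. With lane as a covariate the log2 fold changes in inputs were 0.34 for Eif2s1 and -0.37 for Atf4, each at an edgeR adjusted p of 0.079. In immunoprecipitates they were 0.23 and -0.27 (edgeR adjusted p 0.6 and 0.61). The Eif2s1 call of edgeR in immunoprecipitates was also lost without naive cKI replicate 3 (adjusted p 0.052) or cKI replicates 1, 2 or 3 at 1 h (0.069, 0.062 and 0.058). It was lost too without naive control replicates 2 or 3 (0.099 and 0.1), or control replicates 1 or 3 at 1 h (edgeR adjusted p 0.059 and 0.093).

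**Figure D1:**
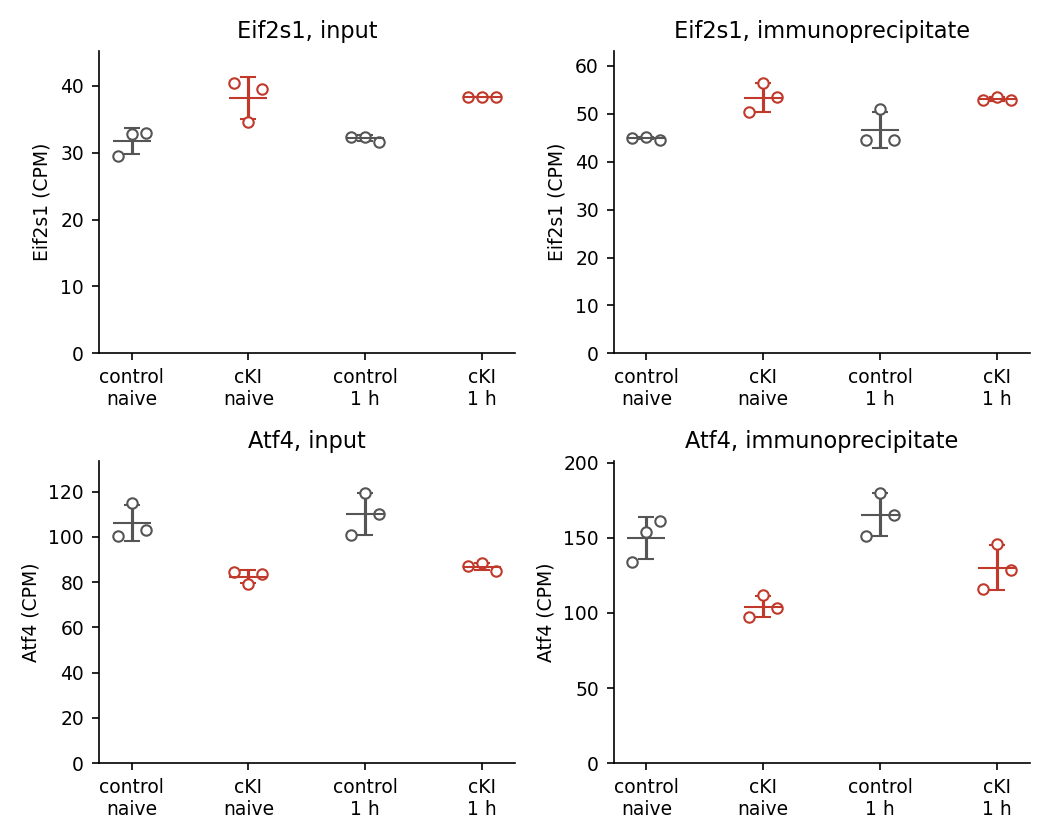
CPM of Eif2s1 and Atf4 (vertical axis) in inputs and immunoprecipitates; open circles are libraries, and the line and whiskers give the mean and SD of 3 mice in each group of genotype and training state. In inputs Eif2s1 lay between 29.6 and 32.9 CPM in naive control mice and between 34.7 and 40.4 CPM in naive cKI mice.

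Immunoprecipitates were rich in transcripts of excitatory neurons and poor in those of glia, vessels, blood and inhibitory neurons. This comparison asks which cells the pulled-down ribosomes came from. Camk2a, the kinase gene whose promoter drove Cre, rose from 2600 ± 260 CPM (SD, n = 12) in inputs to 5160 ± 607 in immunoprecipitates, a log2 fold change of 0.96 (SE 0.07, edgeR adjusted p 1.7e-11). Rpl22, the ribosomal protein that carries the tag, rose from 190 ± 36.7 to 847 ± 155 CPM (log2 2.13, SE 0.09). Gad1, which makes GABA in inhibitory neurons, fell from 293 ± 19.7 to 105 ± 22.9 CPM (log2 -1.51). Gfap of astrocytes was at -3.29 and Mbp of myelin at -3.43. By edgeR 7473 genes were higher and 7523 lower of 17453 tested, and with the mouse as a block 15032 changed.

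Of 20 excitatory neuron markers 18 rose and 0 fell, among them Chn1 (1.27), Nrgn (1.33) and Neurod2 (1.16). Their median log2 fold change was 0.9 (18 calls adjusted over the list alone; camera adjusted p 2.7e-06, p = 0.0043 with an estimated correlation). CA1 markers rose for 10 of 11 and fell for 1 (10 and 1 adjusted over the list alone; camera adjusted p 0.013, p = 0.22 with an estimated correlation). Wfs1 was at 1.76, Pou3f1 at 1.84, Lefty1 at 2.3 and Dcn, a proteoglycan gene that is also in the leptomeningeal list, at -3.54. CA3 markers rose for 11 of 15 and fell for 3 (11 and 3 adjusted over the list alone; camera adjusted p 0.044, p = 0.19 with an estimated correlation). Dentate granule cell markers had a median of 0.03, with 2 of 15 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p 0.93, p = 0.97 with an estimated correlation). All 29 inhibitory neuron markers fell, at a median of -2.33 (29 adjusted over the list alone; camera adjusted p 1.2e-08, p = 0.074 with an estimated correlation). Each measured member also fell among 23 astrocyte markers (median -3.57), 20 oligodendrocyte markers (-4.21), 13 oligodendrocyte precursor markers (-3.83) and 22 microglia markers (-4.66), with the same counts adjusted over the list alone. Camera adjusted p were 1.4e-11, 1.1e-10, 2.6e-07 and 1.4e-10 in that order, with p = 0.0051, p = 0.023, p = 0.0079 and p = 0.0083 with an estimated correlation. Vessel markers fell for 22 of 23 and rose for 1 (22 and 1 adjusted over the list alone; camera adjusted p 6.3e-09, p = 0.01 with an estimated correlation). The 16 leptomeningeal markers fell (16 adjusted over the list alone; camera adjusted p 2e-05, p = 0.087 with an estimated correlation). The 4 blood markers fell as well (4 adjusted over the list alone; camera adjusted p 0.013, p = 0.027 with an estimated correlation). Choroid plexus and ependymal markers fell for 16 of 20 and rose for 1 (17 and 1 adjusted over the list alone; camera adjusted p 0.013, p = 0.37 with an estimated correlation). Markers of thalamus, striatum and cortex went both ways, with medians of -0.6, 0.02 and -0.66. Higher and lower members numbered 3 and 7 of 12, 6 and 4 of 13, and 4 and 7 of 13 (the same adjusted over the list alone). Camera adjusted p were 0.22, 0.77 and 0.74, with p = 0.27, p = 0.75 and p = 0.78 with an estimated correlation.

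**Figure D2:**
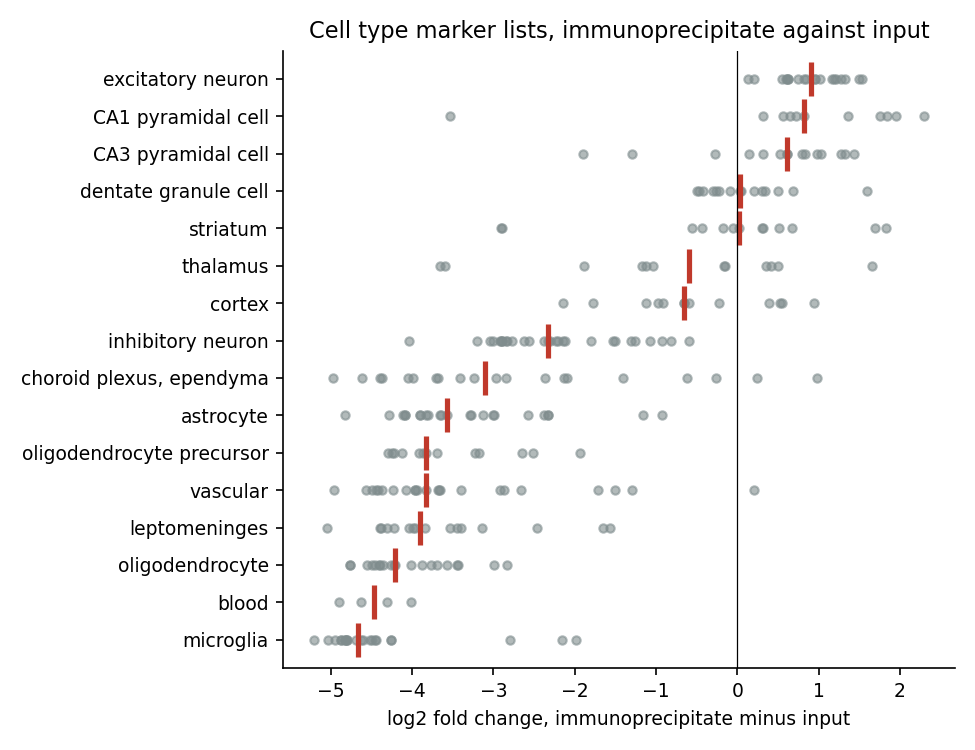
Log2 fold change of immunoprecipitate over input for each measured member of the 16 cell type and region lists, averaged over the 4 groups of mice; grey points are genes and red bars are list medians. Medians run from -4.66 for microglia to 0.9 for excitatory neurons.

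Among functional lists, the 13 genes of the mitochondrial genome fell by the most, with a median of -4.64 and mt-Cytb at -5.14 (13 lower adjusted over the list alone; camera adjusted p 8.7e-07, p = 0.059 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose for 71 of 77 and fell for 2, and mitochondrial ribosomal protein genes rose for 73 of 74 and fell for 1, the same adjusted over the list alone. Camera adjusted p were 7.7e-09 and 4e-11, with p = 0.28 and p = 0.14 with an estimated correlation. Synaptic plasticity genes rose for 32 of 39 and fell for 3 (the same adjusted over the list alone; camera adjusted p 4.8e-06, p = 0.11 with an estimated correlation). Ppp3ca, a calcineurin subunit gene, was at 1.42 and Dlg4, which encodes PSD-95, at 0.98. Initiation factor genes rose for 25 of 32 and fell for 3 (the same adjusted over the list alone; camera adjusted p 0.00035, p = 0.019 with an estimated correlation), Eif4g1 being at 0.88 and Eif2s1 at 0.47. Clock genes rose for 15 of 17 and fell for 1 (camera adjusted p 0.0016, p = 0.045 with an estimated correlation), and heat shock genes rose for 16 of 19 and fell for 2 (0.0044, p = 0.29). Late response genes rose for 15 of 20 and fell for 4 (camera adjusted p 0.0084, p = 0.064 with an estimated correlation). Immediate-early genes rose for 31 of 46 and fell for 8 (camera adjusted p 0.0089, p = 0.32 with an estimated correlation), and endoplasmic reticulum chaperones rose for 18 of 23 and fell for 2 (camera 0.0096, p = 0.28). Cholesterol synthesis genes fell for 12 of 19 and rose for 3 (camera adjusted p 0.044, p = 0.2 with an estimated correlation). The remaining lists did not pass camera. They were ATF4 targets with 27 higher and 13 lower of 44 (adjusted p 0.34, p = 0.57 with an estimated correlation) and transcripts with eIF2α-sensitive reading frames with 14 and 4 of 20 (0.11, p = 0.2). The others were ribosomal proteins with 31 and 25 of 80 (camera adjusted p 0.73, p = 0.91 with an estimated correlation), glucocorticoid genes with 7 and 16 of 25 (0.064, p = 0.25) and interferon genes with 9 and 6 of 23 (0.92, p = 0.97). For all lists from the clock genes on, the counts were the same adjusted over the list alone. The cholesterol list was lost without any 1 of 12 libraries, at camera adjusted p of 0.051 to 0.058. They were the inputs of naive cKI replicates 2 and 3, cKI replicate 1 at 1 h and naive control replicates 2 and 3. Immunoprecipitates among them were naive cKI replicates 1 and 3, cKI replicates 1 and 3 at 1 h, naive control replicates 1 and 2 and control replicate 3 at 1 h.

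In immunoprecipitates of cKI mice, some ATF4 target genes, immediate-early genes and glial markers were lower than in controls, and the first 2 lists lost their calls with lane as a covariate. The genotype comparison asks how transcripts in the immunoprecipitates differ with loss of eIF2α phosphorylation. Glial markers and genes of the mitochondrial genome are depleted by immunoprecipitation, so lower values of these need not reflect ribosomes of Cre-positive cells. Over both training states, edgeR called 100 genes higher and 158 lower. Among 43 ATF4 targets 4 fell (9 adjusted over the list alone; camera adjusted p 0.00065, p = 0.1 with an estimated correlation). The list had a median of -0.01 with lane as a covariate (camera adjusted p 0.3). The 4 were Slc7a3, a transporter of basic amino acids, with a log2 fold change of -0.94 (SE 0.13, edgeR adjusted p 0.0042), Mthfd2 of mitochondrial folate metabolism at -0.54 (SE 0.08, 0.0074), the glycine transporter gene Slc6a9 at -0.52 (SE 0.1, 0.026) and Atf4 itself. Ddit3 was at 0.07 (SE 0.1, edgeR adjusted p 0.73) and Ppp1r15a at -0.05 (SE 0.09, 0.8). Of 46 immediate-early genes 5 fell (14 adjusted over the list alone; camera adjusted p 2.4e-06, p = 0.1 with an estimated correlation). Among them were Fosb (-0.58, SE 0.1), Klf6 (-0.34, SE 0.06), Dusp1 (-0.5, SE 0.1) and Npas4 (-1.07, SE 0.22), while Fos was at -0.71 (SE 0.21, edgeR adjusted p 0.11). The Npas4 call was lost (edgeR adjusted p up to 0.099) in each omission of a library but those of naive control replicate 2 and control replicates 1 and 2 at 1 h. That of Dusp1 was lost (edgeR adjusted p up to 0.077) in each but those of naive cKI replicate 3, cKI replicate 2 at 1 h, naive control replicate 1 and control replicate 1 at 1 h. That of Klf6 was lost without naive control replicates 2 or 3 (edgeR adjusted p 0.078 and 0.064) or control replicate 3 at 1 h (0.052). Their median went from -0.22 to -0.06 with lane as a covariate (camera adjusted p 0.15). Initiation factor genes had 2 members higher and 1 lower (2 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p 0.82, p = 0.69 with an estimated correlation). The members were Eif5, whose protein acts on the initiation complex of eIF2, at 0.3 (SE 0.04, edgeR adjusted p 0.0037), Eif2s1, and Impact, an inhibitor of the eIF2α kinase GCN2, at -0.22 (SE 0.05, 0.034). Myelin and oligodendrocyte markers fell for 3 of 20 (6 adjusted over the list alone; camera adjusted p 0.00017, p = 0.15 with an estimated correlation). Mbp was at -0.45 (SE 0.07) and Mobp at -0.75 (SE 0.13). Of the other cell type lists that immunoprecipitation depletes, those of microglia, leptomeninges, choroid plexus and blood did not pass camera (adjusted p 0.7, 0.088, 0.8 and 0.47; p = 0.79, p = 0.29, p = 0.77 and p = 0.31 with an estimated correlation). Vessel markers had a median of -0.14 with 0 of 20 called by edgeR (0 adjusted over the list alone; camera adjusted p 0.038, p = 0.18 with an estimated correlation), and -0.01 with lane as a covariate (camera adjusted p 0.63). That list was lost without naive cKI replicates 1 or 3 (camera adjusted p 0.09 and 0.059), cKI replicate 1 at 1 h (0.22), naive control replicate 2 (0.12) or control replicates 1 or 2 at 1 h (0.063 and 0.052). Genes of the mitochondrial genome fell for 1 of 11, at a median of -0.46 (7 adjusted over the list alone; camera adjusted p 2.5e-05, p = 0.097 with an estimated correlation). Astrocyte markers had a median of -0.19 with 0 of 23 called by edgeR (4 lower adjusted over the list alone; camera adjusted p 0.00026, p = 0.11 with an estimated correlation). Oligodendrocyte precursor markers fell for 1 of 13 (5 adjusted over the list alone; camera adjusted p 0.0052, p = 0.12 with an estimated correlation; adjusted p 0.075 without naive cKI replicate 1). Inhibitory neuron markers had a median of -0.24 with 0 of 29 called by edgeR (0 adjusted over the list alone; camera adjusted p 0.015, p = 0.42 with an estimated correlation). Their call was lost without naive cKI replicates 1 or 3 (camera adjusted p 0.075 and 0.13), cKI replicate 2 at 1 h (0.16), naive control replicate 2 (0.19) or control replicate 1 at 1 h (0.093). Medians with lane as a covariate were -0.11 for oligodendrocytes, -0.84 for the mitochondrial genome, -0.25 for astrocytes, -0.29 for precursors and -0.39 for inhibitory neurons. Camera adjusted p were 0.039, 4e-07, 0.00021, 0.016 and 0.0091 in that order. The scaffold gene Shank3 was the 1 synaptic plasticity gene that fell, by 0.33 on the log2 scale (10 of 39 adjusted over the list alone; camera adjusted p 0.00028, p = 0.15 with an estimated correlation).

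Single genes with larger differences between genotypes in immunoprecipitates were Ighm, the heavy chain of IgM, at 1.75 (22.7 ± 4.25 against 6.79 ± 1.22 CPM, n = 6), Ifrd2 at 1.62 (7.89 ± 0.439 against 2.71 ± 1.2 CPM) and Mospd3 at -1.11 (12.0 ± 0.924 against 25.9 ± 3.56 CPM). The Wnt ligand gene Wnt4 was at -1.52 (5.81 ± 1.54 against 16.7 ± 3.78 CPM), Deptor, an inhibitor of mTOR, at -0.65, and the receptor gene Ret at -0.76. Serpina3n, which has close relatives that can share reads, was at 0.5 (SE 0.09). Wnt4 and Map3k6 (-2.23) belong to a run of 100 neighbouring measured genes, in GRCm38.p6 gene order, in which 20 genes were called. Atf4, Slc7a3, Mospd3 and Serpina3n have another called gene within 5 measured genes in that order. All 15 granule cell markers were positive, at a median of 0.48 over both training states, though 0 passed edgeR (0 adjusted over the list alone; camera adjusted p 0.0053, p = 0.39 with an estimated correlation). The 79 ribosomal protein genes had a median of 0.11 with 0 calls by edgeR (0 adjusted over the list alone; camera adjusted p 3.5e-05, p = 0.33 with an estimated correlation). Granule cell scores ranged over 2.07 on the log2 scale between immunoprecipitates and over 0.3 between inputs. The granule list was lost without cKI replicate 1 at 1 h (camera adjusted p 0.089) or control replicate 3 at 1 h (0.078), and its median turned to -0.35 with lane as a covariate (camera adjusted p 0.29).

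**Figure D3:**
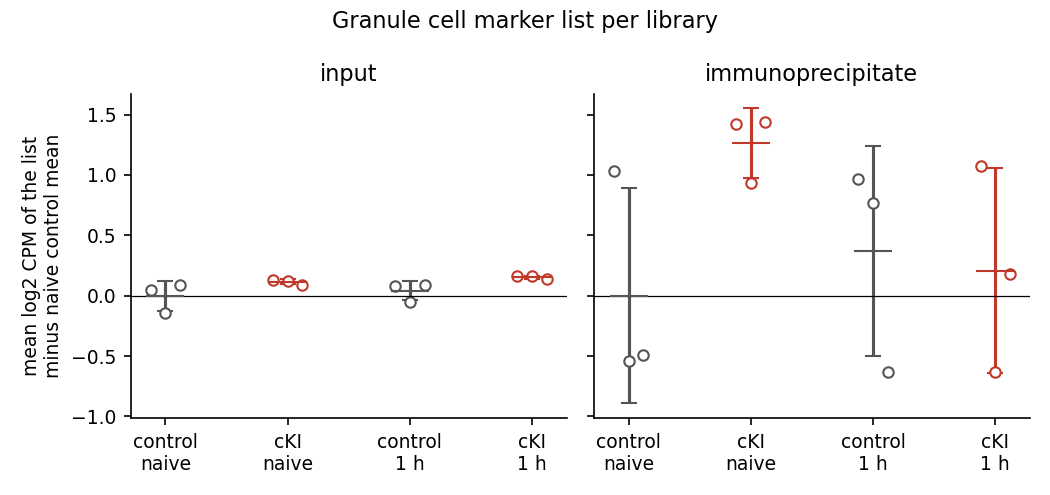
Mean log2 CPM of 15 dentate granule cell markers per library, minus the mean of naive controls of the same fraction; open circles are libraries, and the line and whiskers give the mean and SD of 3 mice. Immunoprecipitates of naive cKI mice lay between 0.93 and 1.44, those of naive controls at 1.03, -0.54 and -0.49, and inputs between -0.14 and 0.16.

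By training state, naive cKI and control immunoprecipitates differed in 564 genes (183 higher, 381 lower) and those at 1 h in 9 (6 higher, 3 lower) by edgeR. The interaction that tests this difference called 2 genes. Mospd3, Wnt4, Ighm and Eif5 passed at 1 h, where 2 of 5 named calls held in every omission of a library. In naive mice 4 immediate-early genes fell (16 lower and 2 higher adjusted over the list alone; camera adjusted p 0.00011, p = 0.17 with an estimated correlation). Dusp1 was at -0.85 (SE 0.15, edgeR adjusted p 0.017) and Nr4a2 at -0.7 (SE 0.15, 0.032). Of 54 named calls in naive mice, 5 held in every omission of a library. CA1 markers fell for 2 of 11 (8 adjusted over the list alone; camera adjusted p 0.00015, p = 0.11 with an estimated correlation). Dcn was at -1.33, but it is also in the leptomeningeal list and was depleted by immunoprecipitation (-3.54), so its fall need not reflect CA1 cells. All 15 granule cell markers were positive at a median of 1.15, with 0 calls by edgeR (0 adjusted over the list alone; camera adjusted p 2.5e-05, p = 0.22 with an estimated correlation). The immediate-early, CA1 and granule lists lost their calls with lane as a covariate, at medians of -0.09, -0.14 and -0.09 (camera adjusted p 0.3, 0.29 and 0.99), and the granule median changed sign. At 1 h the 24 glucocorticoid genes were at a median of -0.12 with 0 calls by edgeR (1 lower adjusted over the list alone; camera adjusted p 0.00011, p = 0.011 with an estimated correlation). With lane as a covariate edgeR called 1 gene in naive mice, 5 at 1 h (6 within lane 6 alone) and 3 over both states, Mospd3 among the last. No lane held both genotypes of naive mice. Of the 564 naive calls 563 kept their sign with that covariate, the median size went from 0.53 to 0.42, and the median SE from 0.11 to 0.2. Without naive cKI replicates 1, 2 or 3 the 564 calls became 255, 147 and 230, and without naive control replicates 1, 2 or 3 they became 933, 22 and 40. The 9 calls became 5, 4 and 3 without cKI replicates 1, 2 and 3 and 5 without control replicates 2 or 3.

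The 258 calls over both states became 119 without naive cKI replicate 1, and 95, 122 and 170 without cKI replicates 1, 2 and 3 at 1 h. They became 395, 52 and 78 without naive control replicates 1, 2 and 3, and 152 and 93 without control replicates 2 and 3 at 1 h. Of 38 named calls, 18 held without any 1 of the 12 libraries, among them Atf4, Slc7a3, Mthfd2, Eif5, Fosb, Mbp, Mobp, Shank3, Wnt4, Deptor, Mospd3, Ighm, Ifrd2 and Map3k6. With lane as a covariate 1 of the 38 was kept, and leaving out a library does not test lane.

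In inputs, some ATF4 targets, heat shock genes and markers of astrocytes and oligodendrocytes were lower in cKI mice than in controls, and 2 microglial markers were higher. Of 44 ATF4 targets 14 fell over both training states (25 adjusted over the list alone; median -0.14, camera adjusted p 4.3e-14, p = 0.0035 with an estimated correlation). They included Chac1, which breaks down glutathione, at -0.64 (SE 0.1, edgeR adjusted p 0.0057), Slc7a3 at -0.52 (SE 0.09, 0.0069) and the asparagine synthetase gene Asns at -0.19 (SE 0.03, 0.0074). Among 19 heat shock genes 8 fell (14 adjusted over the list alone; camera adjusted p 3.8e-09, p = 0.053 with an estimated correlation). Hspb1 was at -1.13 (SE 0.15, edgeR adjusted p 0.0017) and Hsp90aa1 at -0.25 (SE 0.05, 0.011). Astrocyte markers fell for 11 of 23 (15 adjusted over the list alone; camera adjusted p 1e-09, p = 0.0053 with an estimated correlation). Among them were the angiotensinogen gene Agt at -0.53 (SE 0.07), Clu at -0.27 (SE 0.04) and Gfap at -0.16 (SE 0.04, edgeR adjusted p 0.04). Oligodendrocyte markers fell for 10 of 20 (13 adjusted over the list alone; camera adjusted p 2.2e-11, p = 0.061 with an estimated correlation). Mbp fell from 2020 ± 297 to 1530 ± 124 CPM (n = 6), and Mobp was at -0.43. Microglial markers rose for 2 of 22 (9 adjusted over the list alone; camera adjusted p 2.1e-05, p = 0.15 with an estimated correlation), Gpr34 at 0.35 and P2ry13 at 0.32. Granule cell markers rose for 2 of 15 (7 higher and 1 lower adjusted over the list alone; camera adjusted p 0.0004, p = 0.14 with an estimated correlation). Inhibitory neuron markers fell for 7 of 29 (11 adjusted over the list alone; camera adjusted p 0.00031, p = 0.058 with an estimated correlation). The calcium buffer gene Pvalb was at -0.27 and Tac1, which encodes substance P, at -0.42. The inhibitory list lost its call with lane as a covariate (median -0.07, camera adjusted p 0.14). Vessel markers fell for 2 of 23 and oligodendrocyte precursor markers for 3 of 13 (4 and 3 adjusted over the list alone; camera adjusted p 8.8e-06 and 0.00062, p = 0.11 and p = 0.04 with an estimated correlation). Leptomeningeal markers had a median of -0.38 and interferon genes one of 0.19 with 0 calls by edgeR (0 adjusted over the list alone; camera adjusted p 0.0023 and 0.0054, p = 0.34 and p = 0.45 with an estimated correlation). In the fit with lane the precursor list lost its call (camera adjusted p 0.061), and the other 3 stayed past the threshold (0.008, 0.0091 and 3.1e-05). The interferon list was lost without naive cKI replicate 1 (camera adjusted p 0.062), naive control replicate 1 (0.07) or control replicate 2 at 1 h (0.069). Agt, Asns, Chac1, Eif5, Hspb1, Mospd3, Serpina3n and Tac1 have another called gene within 5 measured genes in GRCm38.p6 order.

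Nuclear oxidative phosphorylation genes in inputs were negative for 76 of 77, and 8 fell past edgeR (45 adjusted over the list alone; camera adjusted p 3.6e-16, p = 0.16 with an estimated correlation). One of them, Sdhb (-0.29), lies with Paqr7 (-0.63), Crocc (-0.73) and Arhgef19 (-0.95) in a run of 100 neighbouring measured genes that held 27 calls. Other single genes were Ifrd2 at 1.04, Serpina3n at 0.53, Eif5 at 0.24, Mospd3 at -1.26 and Sod3, an extracellular superoxide dismutase gene, at -1.03. Over both states edgeR called 199 genes higher and 344 lower. Of the calls in immunoprecipitates, 26 higher and 47 lower genes were shared with inputs from the same mice.

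Input calls numbered 148 in naive mice (52 higher, 96 lower) and 46 at 1 h (12 higher, 34 lower). In naive mice ATF4 targets fell for 5 of 44 (19 adjusted over the list alone; camera adjusted p 4.3e-11, p = 0.0074 with an estimated correlation). At 1 h they fell for 3 (12 adjusted over the list alone; camera adjusted p 9.6e-12, p = 0.0062 with an estimated correlation). Glucocorticoid genes fell for 2 of 25 at 1 h, Mfsd2a at -0.7 and Tsc22d3 at -0.47 (10 adjusted over the list alone; camera adjusted p 5.8e-10, p = 0.0069 with an estimated correlation). Of 24 named calls at 1 h, 2 held in every omission of a library, and of 38 in naive mice 19 did. With lane as a covariate edgeR called 133 genes in naive mice (92 within lane 4), 1 at 1 h, where no lane held both genotypes, and 18 over both states. The ATF4 target list then had medians of -0.17, -0.16 and -0.16 in that order (camera adjusted p 1.4e-08, 1.5e-05 and 8.7e-08). In inputs naive control replicate 3 alone separates lane from group, so these values do not settle the part of lane. The 148 calls became 65 and 52 without naive cKI replicates 1 and 2 and 94 without naive control replicate 1. The 46 became 6, 3 and 5 without cKI replicates 1, 2 and 3 and 19 and 23 without control replicates 2 and 3. The 543 became 347 and 280 without naive cKI replicates 1 and 2, and 239, 164 and 208 without cKI replicates 1, 2 and 3 at 1 h. They became 287, 278 and 337 without control replicates 1, 2 and 3 at 1 h. Of 69 named calls over both states 40 held without any 1 of 12 libraries, including Eif2s1, Atf4, Eif5, Chac1, Slc7a3, Asns, Hspb1, Agt, Clu, Mbp and Mobp. With lane as a covariate 6 of the 69 were kept.

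After fear conditioning, immunoprecipitates of control mice held more immediate-early transcripts. Training against naive asks which transcripts in the immunoprecipitates differ 1 h after conditioning. No group had the tone, the shock or handling alone, so learning cannot be told apart from these. Fosb, which encodes a subunit of AP-1, rose from 11.7 ± 1.95 to 28.5 ± 6.14 CPM (SD, n = 3), a log2 fold change of 1.29 (SE 0.15, edgeR adjusted p 0.0024). Egr2 rose by 2.12 (SE 0.36, edgeR adjusted p 0.049), Egr4 by 0.95 (SE 0.17, 0.047) and Errfi1 by 0.49 (SE 0.08, 0.033). Of 46 immediate-early genes 4 passed (17 higher and 1 lower adjusted over the list alone; median 0.39, camera adjusted p 7e-13, p = 0.027 with an estimated correlation). Fos was at 0.89 (SE 0.29, edgeR adjusted p 0.26), Arc at 0.58 (SE 0.27, 0.51) and Npas4 at 0.72 (SE 0.3, 0.43). Egr1 was at 0.83 (SE 0.17, edgeR adjusted p 0.074) and Bdnf at 0.29 (SE 0.11, 0.33). Glucocorticoid genes rose for 1 of 24, Errfi1, which is in both lists (7 adjusted over the list alone; camera adjusted p 7e-07, p = 0.0032 with an estimated correlation). Endoplasmic reticulum chaperones had 0 calls by edgeR at a median of 0.2 (7 higher adjusted over the list alone; camera adjusted p 4e-07, p = 0.048 with an estimated correlation). Cortex markers fell for 1 of 13, Tshz2 at -1.36 (6 adjusted over the list alone; camera adjusted p 2.2e-06, p = 0.019 with an estimated correlation). Vessel markers had a median of 0.37 with 0 of 20 called by edgeR (0 adjusted over the list alone; camera adjusted p 0.0018, p = 0.071 with an estimated correlation). Slc17a6, a glutamate transporter gene of the thalamus list, was at -0.86. Nnt, a mitochondrial transhydrogenase gene, rose by 0.97 (18 to 20.4 CPM in naive mice, 29.3 to 43.9 at 1 h), and Manba, a lysosomal mannosidase gene, was at -1.44 (5.96 ± 1.08 to 2.19 ± 0.277 CPM). In all, edgeR called 24 genes higher and 26 lower, 26 genes with lane as a covariate and 62 within lane 6, which holds all 6 of these libraries. Without naive control replicates 1, 2 or 3 the 50 calls became 14, 9 and 15, and without control replicates 2 or 3 at 1 h they became 10 and 11. Fosb, Nnt, Banp and Manba held without any 1 of the 6 libraries. Leaving out a library does not test an inherited difference between groups of mice, which stays open for Nnt and Manba. In cKI immunoprecipitates of both training states Nnt lay at 23.2 to 27.5 CPM, between the levels of the control groups.

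**Figure D4:**
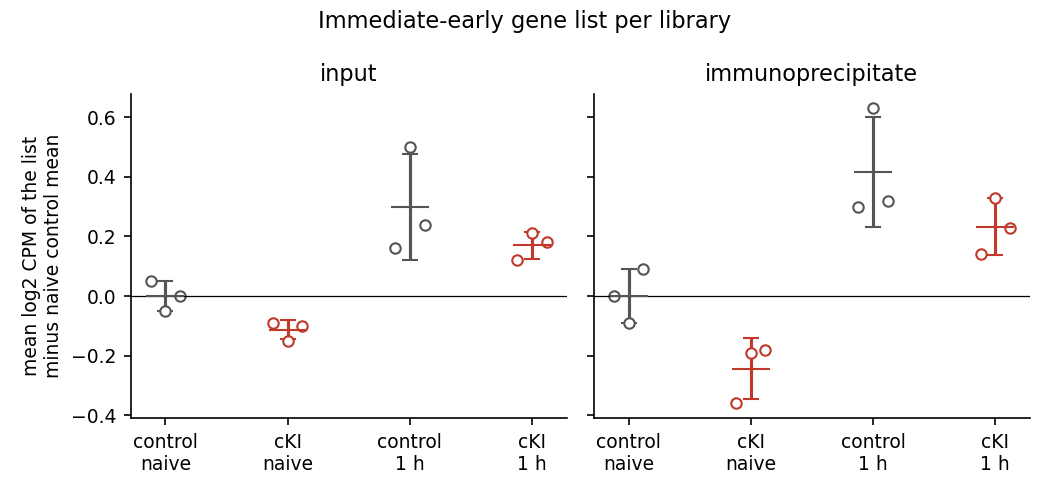
Mean log2 CPM of 46 immediate-early genes per library, minus the mean of naive controls of the same fraction; open circles are libraries, and the line and whiskers give the mean and SD of 3 mice. Immunoprecipitates lay between 0.3 and 0.63 in control mice at 1 h, between 0.14 and 0.33 in cKI mice at 1 h, and between -0.36 and -0.18 in naive cKI mice.

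Inputs of control mice after conditioning showed the same immediate-early list higher, together with glucocorticoid genes and chaperones, and oligodendrocyte markers lower. Fosb rose by 1.55 (SE 0.13, edgeR adjusted p 7.6e-05) and Egr2 by 1.37 (SE 0.27, 0.035). In the list 7 of 46 immediate-early genes rose (21 adjusted over the list alone; median 0.28, camera adjusted p 6.1e-14, p = 0.029 with an estimated correlation). Fos was at 0.97 (SE 0.31, edgeR adjusted p 0.26) and Arc at 0.41 (SE 0.25, 0.56). Of 25 glucocorticoid genes 8 rose (10 adjusted over the list alone; median 0.28, camera adjusted p 3.5e-13, p = 0.0029 with an estimated correlation). They included Tsc22d3, which encodes GILZ, at 0.6 (SE 0.07), Per1 at 0.49 (SE 0.08), Klf15 at 0.44 (SE 0.07) and the kinase gene Sgk1 at 0.93 (SE 0.14). Endoplasmic reticulum genes rose for 6 of 23 (12 adjusted over the list alone; camera adjusted p 3.4e-11, p = 0.037 with an estimated correlation), including the transcription factor gene Xbp1 (0.38) and the disulphide isomerase gene Pdia4 (0.51). Clock genes rose for 3 of 17 (3 adjusted over the list alone; camera adjusted p 0.0002, p = 0.096 with an estimated correlation). Oligodendrocyte markers fell for 11 of 20, all 20 being negative (16 adjusted over the list alone; median -0.42, camera adjusted p 5.8e-18, p = 0.022 with an estimated correlation). Opalin was at -0.67, Cldn11 at -0.55 and Mog at -0.54. Hif3a rose by 1.09 (6.8 ± 0.322 to 14.4 ± 1.01 CPM) and Nnt by 0.91 (17.7 to 18.5 CPM in naive mice, 29.4 to 36.4 at 1 h). Within 5 measured genes of Nnt in GRCm38.p6 order, Fgf10 (0.54), Tmem267 (1.18) and Ccl28 (1.47), named after their values were seen, were called higher too. Etnppl, an astrocyte phospholyase gene, was at -1.15 (22.3 ± 0.465 to 9.96 ± 0.167 CPM). EdgeR called 71 genes higher and 56 lower, and 13 genes with lane as a covariate. Lane 5 held 1 naive control input, so no count within that lane is given here. The 127 calls became 52 without naive control replicate 1 and 33 without control replicate 3 at 1 h. In all 16 of 38 named calls held without any 1 of the 6 libraries, including Fosb, Hif3a, Nnt, Etnppl, Tsc22d3, Per1, Xbp1, Opalin, Mog and Cldn11. With lane as a covariate 6 of the 38 were kept. Leaving out a library does not test an inherited difference between groups of mice either, which stays open for Nnt and its neighbours.

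In cKI mice conditioning was likewise followed by more immediate-early transcripts in both fractions. In immunoprecipitates Fosb rose from 7.71 ± 0.69 to 19.3 ± 1.27 CPM (SD, n = 3), a log2 fold change of 1.33 (SE 0.15, edgeR adjusted p 0.0045). Plk3, a stress-responsive kinase gene, rose by 0.97 (SE 0.1, edgeR adjusted p 0.0028), the ERK phosphatase gene Dusp5 by 0.92 (SE 0.13, 0.028) and Midn by 0.88 (SE 0.13, 0.028). Immediate-early genes rose for 3 of 46 (29 adjusted over the list alone; median 0.38, camera adjusted p 5.4e-16, p = 0.016 with an estimated correlation). Wnt9a fell by 1.13 (SE 0.17, edgeR adjusted p 0.028). In inputs Fosb rose by 1.14 (SE 0.13, edgeR adjusted p 0.0073), and Wnt9a (-0.89, SE 0.11) and Hif3a (-0.71, SE 0.08) fell. The immediate-early list had 1 member higher (17 higher and 2 lower adjusted over the list alone; camera adjusted p 9.8e-18, p = 0.016 with an estimated correlation). Granule cell markers in immunoprecipitates were negative for all 15, at a median of -0.92 with 0 calls by edgeR (0 adjusted over the list alone; camera adjusted p 7.2e-06, p = 0.19 with an estimated correlation), and the call was lost with lane as a covariate (median -0.13, camera adjusted p 0.39). Choroid plexus markers in inputs were at a median of 0.99 with 0 calls by edgeR (0 adjusted over the list alone; camera adjusted p 3.3e-07, p = 0.15 with an estimated correlation). By edgeR 6 genes were higher and 1 lower in immunoprecipitates, and 1 higher and 2 lower in inputs. Lane 5 held 1 cKI immunoprecipitate at 1 h, so no count within that lane is given here. With lane as a covariate edgeR called 0 genes in immunoprecipitates. Without the covariate 1953 genes had an unadjusted p under 0.05, and the DESeq2 Wald test called 125. In inputs edgeR called 3 with lane as a covariate, and 4 within lane 4. Without naive cKI replicates 1, 2 or 3 the 7 calls became 2, 3 and 2, and without replicates 2 or 3 at 1 h 2 and 2, with Fosb and Plk3 kept throughout. The 3 input calls became 0 without naive replicate 1 or replicate 1 at 1 h (edgeR adjusted p 0.059 and 0.078 for Fosb, 0.069 and 0.078 for Wnt9a, 0.059 and 0.076 for Hif3a). Without naive replicate 2 the calls of Fosb and Wnt9a were lost (edgeR adjusted p 0.062 for each), and without replicate 2 at 1 h that of Wnt9a (0.086).

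The interaction of genotype and training, which asks whether cKI and control mice respond differently, called 0 immediate-early genes and showed opposite responses for Hif3a. Medians of the immediate-early list were 0.13 in immunoprecipitates (camera adjusted p 0.16, p = 0.55 with an estimated correlation) and -0.02 in inputs (0.3, p = 0.69), with 0 calls by edgeR in each and 0 adjusted over the list alone. Of all genes, 1423 in immunoprecipitates and 831 in inputs had an unadjusted p under 0.05, and the DESeq2 Wald test called 88 and 27. Hif3a, a hypoxia-inducible factor gene that glucocorticoids induce, rose in control inputs and fell in cKI inputs from 13.1 ± 0.676 to 7.99 ± 0.574 CPM (interaction -1.81, SE 0.12, edgeR adjusted p 7.1e-06, n = 3 per group). Nnt (-0.86, SE 0.1, edgeR adjusted p 0.0054), Adipor2 (-0.46, SE 0.07, 0.024) and Etnppl (1.1, SE 0.15, 0.019) also differed in inputs, and Banp (-0.79, SE 0.1, 0.032) and Manba (1.61, SE 0.22, 0.039) in immunoprecipitates. Several lists passed camera. For glucocorticoid genes the interaction median was -0.22 in inputs (23 of 25 negative, 0 calls by edgeR, 8 adjusted over the list alone; camera adjusted p 1e-12, p = 0.0033 with an estimated correlation). It was -0.16 in immunoprecipitates (19 of 24 negative, 0 calls by edgeR, 4 lower and 1 higher adjusted over the list alone; camera adjusted p 0.0022, p = 0.031 with an estimated correlation). In immunoprecipitates medians were -1.31 for granule cell markers (15 of 15 negative) and 0.5 for CA1 markers (11 of 11 positive), with 0 calls by edgeR and 0 adjusted over the list alone. Camera adjusted p were 3.1e-06 and 6.9e-05 (p = 0.18 and p = 0.098 with an estimated correlation), and with lane as a covariate the medians were -0.6 and 0.24 (camera adjusted p 0.052 and 0.018). Ribosomal protein genes had a median of -0.21 there and chaperones one of -0.26, with 0 calls by edgeR (0 and 4 lower adjusted over the list alone; camera adjusted p 7.2e-08 and 4e-04, p = 0.22 and p = 0.14 with an estimated correlation). In inputs medians were 0.24 for oligodendrocyte markers, -0.09 for chaperones and -0.11 for clock genes, again with 0 calls by edgeR. Adjusted over each list alone, 2 were higher, 6 lower and 0 changed in that order (camera adjusted p 1.1e-09, 1.7e-05 and 0.00083, p = 0.082, p = 0.13 and p = 0.13 with an estimated correlation). In all edgeR called 2 genes in immunoprecipitates and 6 in inputs, and 0 and 1 with lane as a covariate, the 1 being Hif3a. The 2 calls became 5 without naive control replicate 1 or control replicate 1 at 1 h, 1 without naive control replicate 3 and 0 without any other library. The 6 became 3 without cKI replicates 1 or 2 at 1 h or control replicates 2 or 3 at 1 h, 18 without naive control replicate 2 and 13 without control replicate 1 at 1 h.

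Ratios of immunoprecipitate to input, which set transcripts on ribosomes against the whole tissue, differed between genotypes in few single genes and in several lists. With genotype 2731 of 17453 genes had an unadjusted p under 0.05, the DESeq2 Wald test called 24 and edgeR 4, namely Wnt4 (-1.22, SE 0.19, adjusted p 0.031), Muc3a (-1.27, SE 0.22, 0.044), Il17rd (0.93, SE 0.15, 0.031) and Lgi3 (0.35, SE 0.06, 0.044). Wnt4 was at 18.7 and 14.7 CPM in control immunoprecipitates (naive and 1 h) and at 6.46 and 5.17 in cKI immunoprecipitates. Atf4 was at -0.08 (SE 0.09, edgeR adjusted p 0.66) and Eif2s1 at -0.04 (SE 0.06, 0.76). Nuclear oxidative phosphorylation genes were positive for 76 of 77 with 0 calls by edgeR (41 adjusted over the list alone; median 0.25, camera adjusted p 3.9e-17, p = 0.12 with an estimated correlation). Mitochondrial ribosomal protein genes were positive for 74 of 74 (1 adjusted over the list alone; median 0.18, camera adjusted p 2.4e-13, p = 0.1 with an estimated correlation). Ribosomal protein genes were positive for 73 of 80 (0 adjusted over the list alone; median 0.23, camera adjusted p 2.2e-09, p = 0.18 with an estimated correlation). Genes of the mitochondrial genome were negative for 12 of 13 (7 adjusted over the list alone; median -0.51, camera adjusted p 8.7e-07, p = 0.059 with an estimated correlation). Synaptic plasticity genes were negative for 32 of 39 and CA1 markers for 10 of 11, at medians of -0.15 and -0.14 (0 adjusted over the list alone; camera adjusted p 1.9e-06 and 0.0052, p = 0.095 and p = 0.17 with an estimated correlation). In these 6 lists, oxidative phosphorylation included, edgeR called 0 genes, and each list passed camera without any 1 of the 24 libraries. Immediate-early genes had a median of -0.12 with 0 calls by edgeR (2 lower adjusted over the list alone; camera adjusted p 0.0056, p = 0.3 with an estimated correlation). Their list was lost without the immunoprecipitates of naive cKI replicate 1 (camera adjusted p 0.062) or control replicate 2 at 1 h (0.096). With training 720 genes had an unadjusted p under 0.05 and the Wald test called 5. Plk3 was the 1 gene called by edgeR (0.67, SE 0.1, adjusted p 0.009), and immediate-early genes had a median of 0.14 with 0 calls by edgeR (2 higher adjusted over the list alone; camera adjusted p 6e-05, p = 0.15 with an estimated correlation). With the mouse as a block edgeR called 1 gene with genotype, Wnt4 (adjusted p 0.0057), and 1 with training, which was not Plk3 (0.12). Lane, which differs between genotypes in both fractions, was not run as a covariate for these ratios, for genes or for lists. The 4 genotype calls became 13 without the immunoprecipitate of naive control replicate 1 and 2 without that of control replicate 2 at 1 h or the input of naive control replicate 2. They became 3 or 4 without the immunoprecipitates of naive cKI replicates 1, 2 or 3, cKI replicate 2 at 1 h or control replicate 1 at 1 h, and 0 without any other library. The 1 training call became 3 without the input of naive control replicate 2 or the immunoprecipitate of naive control replicate 1. It became 2 without the immunoprecipitates of naive cKI replicate 3 or control replicate 2 at 1 h, and remained 1 otherwise.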

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

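The tests of the granule cell spread, of cell type and depth for the input that stood apart, of neighbours among training calls and of runs of 100 genes were chosen only after the result was seen. The same holds for the granule cell score as a covariate, for the ratio of folds with lane as a covariate and for lane with 1 input left out.

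A difference between cKI and control mice in the response to conditioning drew attention to 6 genes and 1 list in inputs. Hif3a rose in control inputs (6.8 ± 0.322 to 14.4 ± 1.01 CPM) and fell in cKI inputs (13.1 ± 0.676 to 7.99 ± 0.574 CPM), an interaction of -1.81 (edgeR adjusted p 7.1e-06). Over the alternatives its adjusted p stayed between 5.7e-31 and 0.0013, and between 4.5e-06 and 8e-05 with 1 of 12 libraries left out. Nnt had an interaction of -0.86 (edgeR adjusted p 0.0054; 4.5e-09 to 0.12 over the alternatives, the highest with lane as a covariate and 1 input left out), and the clone AC154550.1 one of -0.85 (0.0054). Etnppl was at 1.1 (edgeR adjusted p 0.019; 1.1e-06 to 0.15, the highest with lane as a covariate), and its call was lost without cKI replicates 1 or 2 at 1 h, naive control replicates 1 or 3 or control replicates 2 or 3 at 1 h (adjusted p up to 0.093). Adipor2 was at -0.46 (edgeR adjusted p 0.024; 6.9e-07 to 0.41), with the call lost (up to 0.14) in each omission but those of naive cKI replicate 2, naive control replicates 1 and 2 and control replicate 1 at 1 h. The clone A730081D07Rik was at 2.9 (edgeR adjusted p 0.034). Both clones were named after their values were seen. Glucocorticoid genes had a median interaction of -0.22 in inputs (camera adjusted p 1e-12, p = 0.0033 with an estimated correlation; -0.38 and 1.6e-12 with lane as a covariate).

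In immunoprecipitates the same kind of difference was seen for Banp at -0.79 (edgeR adjusted p 0.032) and Manba at 1.61 (0.039). Each call was lost with lane as a covariate (adjusted p 0.5), with the granule cell score as a covariate (0.24 and 0.37) and in each omission of a library but those of naive control replicate 1 and control replicate 1 at 1 h (up to 0.13 and 0.17). The DESeq2 Wald test gave adjusted p of 1.5e-08 and 1.4e-06. Glucocorticoid genes had a median interaction of -0.16 (camera adjusted p 0.0022, p = 0.031 with an estimated correlation), while granule cell markers were at -1.31 (3.1e-06, p = 0.18) and CA1 markers at 0.5 (6.9e-05, p = 0.098). Of 100 splits of the 12 immunoprecipitates, 4 gave at least the 2 interaction calls of the real one, and the highest other gave 776. Of 100 splits of the inputs, 2 gave at least the 6 calls of the real one, and the highest other gave 8. Both shares are under 0.05, but these splits mix the labels of all groups, so effects of genotype or training can enter them. The shares therefore do not test the interaction by itself. Splits of the immunoprecipitates that called 616 and 776 genes had contrasts of granule cell scores of 1.27 and -1.28, against -0.71 for the real split. Their contrasts of lane numbers were -0.33 and 0.67, against 0.33 for the real split.

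Differences in the ratio of immunoprecipitate to input were seen with genotype for Wnt4 at -1.22 (edgeR adjusted p 0.031; 5.8e-06 to 0.067 over the alternatives), Il17rd at 0.93 (0.031; 6e-05 to 0.22), Muc3a at -1.27 (0.044; 0.0048 to 0.15) and Lgi3 at 0.35 (0.044; 1.8e-05 to 0.22). Their calls were lost in 16, 17, 20 and 19 of 24 omissions of a library, with adjusted p up to 0.1, 0.1, 0.14 and 0.15. Lane was not among the alternatives for ratios of immunoprecipitate to input, so its part in them is open. Each omission of an input ended all 4 calls, except that of naive control replicate 2 for Wnt4 and Il17rd. With training they were seen for Plk3 at 0.67 (edgeR adjusted p 0.009; 1.4e-05 to 0.12, the highest with the mouse as a block), whose call was lost in 0 of 24 omissions. By camera 9 lists passed, and 3 of them had p under 0.05 with an estimated correlation too, namely vessel markers at 0.25 (adjusted p 1.4e-06, p = 0.026 with an estimated correlation), cortex markers at -0.26 (9.5e-05, p = 0.028) and cholesterol synthesis genes at 0.08 (0.00049, p = 0.045). Of 60 splits, 2 gave at least the 4 genotype calls (highest other 203) and 2 at least the 1 training call (highest other 1). Both shares are under 0.05, and the split with 203 calls points to a structure of the samples.

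Granule cell markers varied by 2.07 on the log2 scale between immunoprecipitates, and the tables argue against uneven dissection (a range of 0.3 over inputs of the same mice), against lane as the whole cause (a range of 1.66 within lane 6) and against genotype as the whole cause (1.66 within the 6 control immunoprecipitates). The 6 control immunoprecipitates all lie in lane 6, so both ranges of 1.66 come from overlapping libraries and are not independent arguments. In the fit with the granule cell score the median ratio of adjusted to unadjusted log2 fold change over the 564 naive calls was 0.834 (quartiles 0.698 and 0.975). The score is a proxy from marker genes that itself differs between the groups compared. The ratio therefore leaves an uneven share of granule cells open as their cause. All 564 kept their sign and an unadjusted p under 0.05, but 27 calls were left, since the median size fell from 0.53 to 0.42 and the median SE went from 0.11 to 0.12. Lane as a covariate gave a similar ratio of 0.855 (quartiles 0.657 and 1.039) and the same fall in size, with 563 signs kept, but the median SE went from 0.11 to 0.2, 1 call was left and 282 had an unadjusted p under 0.05. Lane stays open for the naive calls, since no lane held both genotypes and cKI replicate 1 at 1 h alone separates lane from group in immunoprecipitates, and for the spread of the granule cell markers a recovery of their ribosomes that differs between mice was not tested.

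Replicate 3 of the naive cKI inputs had mt-Nd6 at 680 CPM against 26.3 to 36.1 in the other inputs, and Ppia at 4.22 against 253 to 342. The tables argue against RNA from another cell type (largest excess of a marker score -0.07) and against lower depth (30.1 M counts). Opposite-strand genes had a median deviation of 0.02, against -0.12 to 0.17 in other inputs. These 69 genes did not rise as a set, but the test was not made on the 150 genes that lay apart. Counting without regard to strand is therefore not excluded. Of the genes over 4-fold away that could be placed, 59.2% overlap another annotated gene, against 47.9% of other genes (one-sided Fisher's exact test p 0.031). Another assignment of reads in overlapping genes cannot be told apart from other sources, because only 76 of the 150 genes could be placed. Apart from RNA of another cell type, no biological explanation was tested.

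Genotype calls lay next to each other more often than random genes in GRCm38.p6 order. In immunoprecipitates 68 of 245 placed calls had another call among the 5 nearest measured genes on either side (random draws 24 to 53, one-sided permutation p 3e-04), and in inputs 184 of 512 (117 to 168, one-sided p 9e-04). The densest run of 100 measured genes held 20 calls in immunoprecipitates (expected 1.74, highest random 11) and 27 in inputs (expected 3.31, highest random 15), each at a one-sided permutation p of 0.001, the smallest that 1000 draws can give. A candidate explanation is a strain or linked variant carried with the alleles, which may hold for Wnt4, Map3k6, Paqr7, Arhgef19, Crocc and Sdhb in these runs. It cannot be set aside for Atf4, Slc7a3, Chac1, Asns, Tac1, Eif5, Hspb1, Agt, Serpina3n and Mospd3, which have a called neighbour outside them. For a single gene such a neighbour says little, since random draws had medians of 38 calls with a neighbour in immunoprecipitates and 142 in inputs. For training calls in control mice a strain or linked variant stays open in immunoprecipitates (0 of 48, within the random 0 to 6) and in inputs (17 of 123, random 2 to 18, one-sided permutation p 0.037, Nnt and Manba among them). An effect of eIF2α itself on neighbouring genes was not tested.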

How the results depend on the processing

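Camera without each library in turn, the granule cell score as a covariate, and lane together with 1 input left out were tests chosen only after the result was seen. With DESeq2 size factors every count of calls stayed within 1.5 times its value. Over all alternatives 22493 values of the named genes kept for the text stayed on their side of the threshold. Another 1684 kept the direction but lost the call, 253 gained one, and 0 with a call in either fit turned. Turns of values without a call in either fit were not counted. For called lists 2339 kept their direction and call, 580 lost the call and 16 turned. Counts below run in the order naive genotype, genotype at 1 h, genotype over both states, training in controls, training in cKI mice and interaction, and cover those that moved by more than 1.5 times. The cause was not tested except where the setting itself shows it. The DESeq2 Wald test gave 1246, 45, 752, 257, 125 and 88 in immunoprecipitates, 522, 165, 952, 289, 22 and 27 in inputs, and 24 and 5 for the interactions of fraction with genotype and training. With replicate number as a block, immunoprecipitates gave 1018 and 467 for naive genotype and genotype over both states, 32 for training in cKI mice and 4 for the interaction, and inputs gave 93, 17 and 292 for the genotype contrasts. With the mouse as a block, fraction by genotype gave 1. Lane as a covariate gave 1, 5, 3, 26, 0 and 0 in immunoprecipitates and, except for naive genotype and training in cKI mice, 1, 18, 13 and 1 in inputs. For the 2 counts of 0, without the covariate, 1953 and 1423 genes had an unadjusted p under 0.05 by edgeR. Lane with naive cKI replicate 3 left out gave 69, 3, 40, 15, 1 and 1 in inputs. Only the 2 groups compared gave 369, 5, 87 and 1 in immunoprecipitates and 36, 498, 21 and 17 in inputs, for the contrasts of 2 groups. No filter gave 22 for genotype at 1 h, 112 and 25 for training in control and cKI mice and 16 for the interaction in immunoprecipitates, 10 for the interaction in inputs and 1 for fraction by genotype. Within single lanes, with fewer libraries, naive genotype in inputs gave 92 (lane 4), training in control inputs 29 (lane 5) and training in cKI immunoprecipitates 0 (lane 5). Both lane 5 fits set 3 libraries against 1, the single ones being 1 naive control input and 1 cKI immunoprecipitate at 1 h. A single library gives no spread for its group, so no conclusion is drawn from these 2 counts. Single lanes were not run for naive genotype in immunoprecipitates and genotype at 1 h in inputs, which no lane holds. The granule cell score gave 27 for naive genotype, 117 and 2 for training in control and cKI mice and 0 for the interaction in immunoprecipitates.

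With 1 library left out, counts in immunoprecipitates ranged from 22 to 933, 3 to 7, 52 to 395, 9 to 49, 2 to 6 and 0 to 5 in the same order. In inputs they ranged from 52 to 131, 3 to 35, 164 to 741, 33 to 125, 0 to 4 and 3 to 18. Immunoprecipitate against input ranged from 15042 to 15168, and the interactions of fraction with genotype and training from 0 to 13 and from 1 to 3. Where a group keeps 2 libraries, the fit takes its spread from all groups.

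Lane as a covariate turned the direction of the camera test for granule cell markers (median -0.35) and vessel markers (-0.01, a median still negative) for genotype over both states in immunoprecipitates. In inputs it turned ribosomal proteins (0.03) and synaptic plasticity genes (-0.05) for training in controls. For the interaction in inputs it turned mitochondrial ribosomal proteins (-0.02), oxidative phosphorylation (-0.02) and choroid plexus markers (0.03, a median still positive). The test of 9 lists turned without 1 library. Without naive cKI replicate 2 these were oxidative phosphorylation for naive genotype (medians 0 to 0.17 over omissions) and for the interaction (-0.17 to 0.04) in immunoprecipitates. Without naive control replicate 2, in inputs, ribosomal proteins and synaptic plasticity genes turned for naive genotype (-0.16 to 0.02 and -0.01 to 0.13) and for training in controls (-0.15 to 0.01 and -0.01 to 0.13). Without the same library mitochondrial ribosomal proteins (-0.01 to 0.1) and oxidative phosphorylation (-0.03 to 0.12) turned for the interaction. Without cKI replicate 1 at 1 h vessel markers turned for training in cKI inputs (-0.13 to 0.03). At the lowest depth 1 count equals 0.035 CPM, which limits genes near that level.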

Other observations

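The per-mouse levels of Wdfy1, Nnt and Gm10073 and the neighbours of training calls were chosen as tests only after the result was seen. Wdfy1 had 2 levels that matched between the input and the immunoprecipitate of a mouse. Naive controls and naive cKI replicates 1 and 3 lay at 53.3 to 57.6 CPM in inputs and 46.8 to 49.4 in immunoprecipitates. The other 7 mice lay at 35.8 to 37.2 and 26.2 to 30.8 CPM. Gm10073 was at 3.64 to 9.14 CPM in cKI inputs, and at 0, 0.0256 or 0.031 CPM in control inputs, with 0 in all control immunoprecipitates. Nnt, which is known to differ between substrains of C57BL/6 mice, was at 17.7 to 18.5 CPM in naive control inputs, 29.4 to 36.4 in control inputs at 1 h and 24.6 to 26.7 in cKI inputs. A hypothesis is that inherited variants of the strain background differ between the groups of mice and may account for part of the genotype and training calls. For genotype calls, neighbours (68 in immunoprecipitates and 184 in inputs) are consistent with it, and for training calls in control immunoprecipitates the 0 neighbours of 48 calls, within the random 0 to 6, leave it open. In control inputs 17 of 123 training calls had a called neighbour (random 2 to 18, one-sided permutation p 0.037), among them Nnt with Fgf10, Tmem267 and Ccl28, which leaves it open as well.

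The splits of the libraries were planned. For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many calls as the real one in each. In immunoprecipitates the real and the highest other counts were 564 and 0 for naive genotype, 9 and 0 for genotype at 1 h, 50 and 0 for training in controls and 7 and 1 for training in cKI mice. In inputs they were 148 and 0, 46 and 1, 127 and 2, and 3 and 1. For genotype over both states, 3 of 100 splits of the immunoprecipitates gave at least the 258 calls, so the share is under 0.05. The highest other gave 925, which points to a structure of the samples, and its contrast of granule cell scores was 1.28 against 0.55 for the real split. The same contrast of lane numbers was -0.67 in each of these splits, so granule cells and lane are not told apart as its source. In inputs 1 of 100 splits gave the 543 calls (highest other 6), and for immunoprecipitate against input 1 of 60 gave the 14996 calls (highest other 8115).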
